A study of Rattus norvegicus with 24 samples.

How the data were processed

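Gene expression was measured by RNA sequencing in lung tissue of 24 male Fischer rats, 6 animals in each of 4 groups. The labels describe whole-body inhalation of air, crystalline silica at 15 mg/m3 for a short period early in the study, cigarette smoke at 80 mg/m3 after a lower starting level, or silica and smoke, with a total of 29 weeks. The starting level in week 1 was 40 mg/m3 in the smoke group and 45 mg/m3 in the group that received both. The group that received both is called the combined group here. Replicates were numbered within a group in the order of deposit, so a number names a library and pairs nothing. Each group holds separate animals per the labels.

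The authors deposited a table of whole-number read counts per gene, not normalized, with 1 column per library. Per the submitters' processing notes, the tools were bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, Cufflinks, SAMtools 1.8 and HTSeq 0.11.2, and the genome build and annotation are not given in the sources used here. Per the labels' protocols, libraries came from total RNA with ribosomal RNA removed and a kit that keeps strand. The strand setting of the counting is not given in the sources used here, so overlapping genes and near-identical family members, such as the haemoglobin genes, are uncertain. The table held 30069 lines, of which 26 repeated the symbol and counts of another line and were removed, leaving 30043 genes. Older gene symbols were matched through a RefSeq gene table of assembly GRCr8, which was used for names only.

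Total counts ran from 21629 in smoke 2 to 4687805 in air 6, with a median of 2335358. A gene seen with 3 counts stands at 1.28 CPM (counts scaled to the library's own total) in a library of median depth and at 139 CPM in smoke 2, so low genes could not be measured there. CPM of single libraries use that total, and group means and SD of CPM use the total scaled by TMM, so they differ slightly. Intervals on shares of counts are exact binomial intervals and cover counting error only. Between libraries of 1 group the lowest chi-square per degree of freedom was 1.80, so no such pair agreed within sampling noise. Pairs across groups were not compared. Repeat libraries of 1 animal could also differ by more than counting noise, so the values do not show separate animals. All 24 were counted as separate animals per the labels.

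Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 13322, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 24 libraries with 20 residual degrees of freedom. The comparisons were silica with air, smoke with air, combined with air, combined with silica, combined with smoke, and the interaction. The interaction asks whether the log2 effect of both differed from the sum of the log2 effects of each. Tests were two-sided and Benjamini-Hochberg adjusted p under 0.05 was called. Values after ± are standard errors of a log2 fold change unless marked SD. They were derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

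Gene lists numbering 24 were fixed before the data were examined, as were the model, the comparisons, the naming rule and the first set of alternatives. Of 331 listed members 330 were found and 283 were tested. The adipocyte list had 1 tested member and the mast cell list 2, too few for a test, and the other 22 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists were aryl hydrocarbon receptor targets, NRF2 antioxidant targets, cytokines and chemokines, neutrophil markers, macrophage markers, lipid-laden macrophage and lysosome genes, complement and acute phase genes, extracellular matrix and fibrosis genes, alveolar type 2 and surfactant genes, alveolar type 1 markers, airway secretory genes, ciliated cell genes, B and plasma cell markers, T and NK cell markers, endothelial markers, interferon-stimulated genes, MHC class II genes, proliferation genes, cholesterol synthesis genes, circadian clock genes, cardiac muscle markers, adipocyte markers, mast cell markers and erythroid genes.

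The naming rule took, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among called genes with a mean of at least 1 CPM and all 6 libraries of a group above all 6 of the other. It also took up to 4 called members and the 2 most abundant members not called of each list, the 5 interaction genes with the smallest p where fewer than 3 were called, and 10 genes in every comparison: Cyp1a1, Cyp1b1, Nqo1, Ccl2, Spp1, Lcn2, Mmp12, Chi3l1, Sftpc and Col1a1. Cyp1a1 was too low to be tested. Of the 247 called results the rule took, 179 were called whichever single library was left out and 240 without silica 1, smoke 1 and smoke 2. Sentences were given to 127 of them, picked partly after this stability had been seen (112 of the 127 held without each library), so the genes described are more stable than the 247.

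A silica response score and a smoke response score were computed per library as the mean of log2 CPM differences from the air mean over genes called for the average effect of that exposure with an absolute log2 change of at least 1, signed by direction. These genes were chosen on the same libraries. Scores were compared by exact permutation tests, or with 100000 permutations for the interaction. The agreement of an exposure's effect with and without the other was measured only between comparisons that share no library. A clock score used 9 clock genes called for the average smoke effect without silica 1, smoke 1 and smoke 2, and a score of other smoke genes used the 20 called there outside the clock list and not called for silica. The latter replaced a reading of hand-picked Zbtb16, Tsc22d3 and Cd163, since smoke 1 had taken part in choosing them. The new score decided nothing on an inflamed lung in a smoke-exposed animal for smoke 1. The clock score argued against it and Zbtb16 did not, so it stays open. The score was chosen after these values had been seen.

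The model was tested on simulated counts with known changes over 13156 genes. All simulated libraries shared 1 mean profile, with the depths and the spread per gene taken from the real data. Every silica and combined library received the full change. Libraries that depart from their group, as silica 1, smoke 1 and smoke 2 do, were not simulated, so the shares hold for a cleaner setting. For silica against air, edgeR recovered 53.8% of 65 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 95.4% of 65 changed 4-fold, with 7 false calls. For the combined group against smoke the shares were 53.8%, 86.6% and 96.9% with 14 false calls, and for smoke against air, simulated with no change, there were 0 calls. Alternatives tried were other scalings, no filter, an added filter at a mean of 1 CPM in a group, DESeq2 1.42.0, limma voom, only the 12 libraries compared, 1 surrogate variable (sva 3.50.0), a test against a 1.2-fold change, a minimum 1.5-fold change, adjusted p under 0.01, and leaving out each library. The filter at 1 CPM was already met by the genes kept by filterByExpr, so it could change nothing. Chosen after seeing the data were the analysis without silica 1, smoke 1 and smoke 2, voom with library quality weights, and leaving out each library for the lists and for the agreement across genes. No library was moved to another group.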

Results

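Lung RNA of 24 rats in a study of 29 weeks was counted per gene. They had breathed air, crystalline silica (a mineral dust that injures the lung) for 5 days in week 3, cigarette smoke, or both (the combined group), with 6 animals in each group. Depth was uneven. Smoke 2 held 21629 counts and silica 4 held 280484, and the other libraries held 1084815 to 4687805. In smoke 2, haemoglobin transcripts took 56.0% of the counts (exact binomial interval 55.3% to 56.6%), against 0.249% to 1.54% in the others, and 3469 genes had a count, against 13635 in silica 4 and 16413 to 18971 elsewhere. The library labelled silica 1 had Mmp12, a macrophage elastase, at 3.26 CPM where the other silica libraries had at least 57.0 CPM. The library labelled smoke 1 had it at 57.9 CPM where the other smoke libraries had at most 11.9 CPM. Labels were kept as deposited, and counts are also given without silica 1, smoke 1 and smoke 2, an analysis chosen after seeing the data. That analysis keeps air 6, so its comparisons with air still hold that library. The voom quality weight of air 6 was 0.269, against 0.251 in smoke 2, 0.520 in silica 1 and 0.733 in smoke 1.

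**Figure D1:**
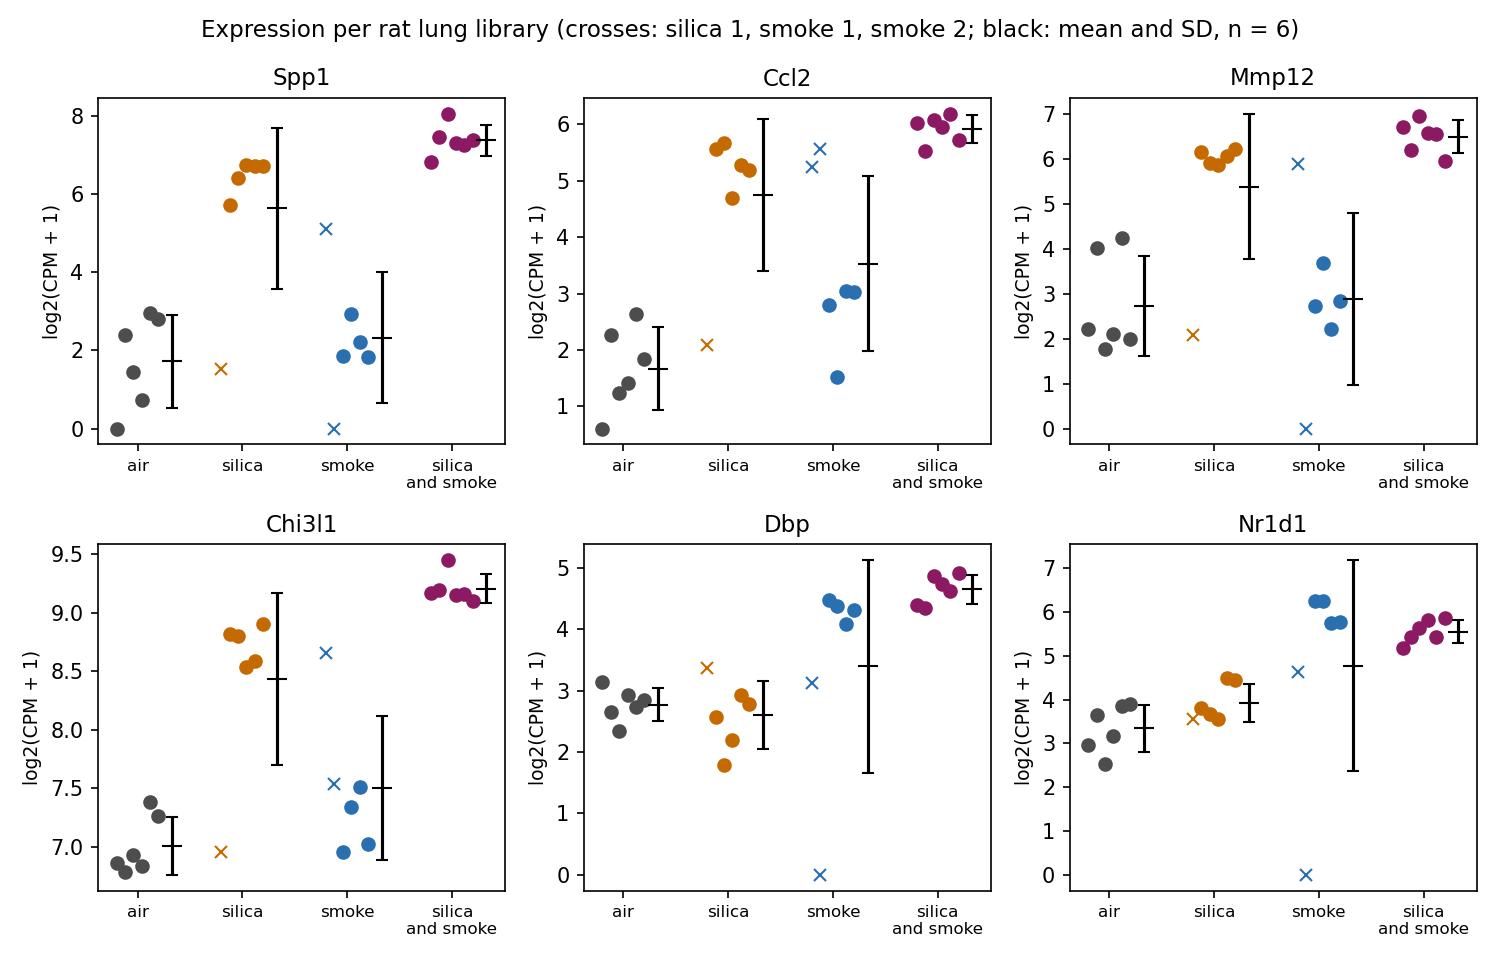
Expression of Spp1, Ccl2, Mmp12, Chi3l1, Dbp and Nr1d1 as log2(CPM + 1) in each of the 24 libraries by group, with the group mean and SD in black and crosses for the libraries labelled silica 1, smoke 1 and smoke 2. Mean Spp1 was 3.19 CPM in air, 77.1 CPM in silica, 8.07 CPM in smoke and 175 CPM in the combined group.

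The first comparison asked what silica alone changed. Chemokine transcripts were far higher after silica (n = 6 and 6): Spp1 (osteopontin, a secreted matrix and signalling protein, gene identifier 25353) rose from 3.19 ± 2.81 to 77.1 ± 43.2 CPM (SD), a log2 fold change of 4.39 ± 0.60 (edgeR adjusted p = 3.17e-04). Ccl2 (24770) and Ccl7, which attract monocytes, rose by 3.75 ± 0.54 and 3.42 ± 0.52 on the log2 scale. S100a9 and S100a8, the calprotectin subunits of neutrophils, rose by 2.88 ± 0.40 and 1.82 ± 0.32, and Chia, an acidic chitinase of the airway, by 2.64 ± 0.37. Mmp12 (117033) rose by 3.00 ± 0.56, the fatty acid carrier Fabp4 by 1.88 ± 0.27 and the chitinase-like Chi3l1 (89824) by 1.56 ± 0.25. In every silica library the inhibitory receptor Lilrb4 stood above every air library (1.36 ± 0.20), and the endophilin-family gene Sh3glb2 stood below (-0.84 ± 0.18). With limma voom Spp1 (adjusted p = 0.151), Ccl2 (0.117), Ccl7 (0.122) and Mmp12 (0.0718) did not pass, at log2 values of 4.11, 3.47, 3.11 and 3.005. Sh3glb2 did not pass with DESeq2 (adjusted p = 0.0519), with its 12 libraries only (0.0523), against 1.2-fold (0.0505) or with 1 surrogate variable (-0.60, 0.253).

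Of 15 tested cytokine and chemokine genes 8 were higher, 0 lower and 7 did not pass (12 higher when adjusted over the list alone), with a camera adjusted p of 4.15e-15 that held with an estimated correlation (adjusted p = 0.0379). Among them the inflammatory cytokine Il1b rose by 0.91 ± 0.18. Of 9 neutrophil markers 5 were higher and 4 did not pass (7 adjusted over the list alone), including the decoy receptor Il1r2 at 2.51 ± 0.44, with camera adjusted p = 3.77e-11 and adjusted p = 0.0379 with an estimated correlation. Complement and acute phase genes had 8 of 19 higher and 11 not passing (14 adjusted over the list alone), led by the complement regulator Cfi at 2.52 ± 0.41, the central component C3 at 1.53 ± 0.28, haptoglobin (Hp) at 1.30 ± 0.25 and factor B (Cfb) at 1.07 ± 0.22. Their camera adjusted p of 3.96e-15 was lost (adjusted p = 0.0627 with an estimated correlation). Lipid-laden macrophage and lysosome genes had 8 of 20 higher and 12 not passing (16 adjusted over the list alone), with camera adjusted p = 2.61e-14 and adjusted p = 0.103 with an estimated correlation. Macrophage markers had 3 of 13 higher and 10 not passing (8 adjusted over the list alone), with camera adjusted p = 5.38e-05 and adjusted p = 0.187 with an estimated correlation. The sialic acid receptor Siglec1 rose by 0.86 ± 0.19 (adjusted p = 0.0549 without silica 5), and Csf1r, the receptor that macrophages need, stood at 0.03 ± 0.07 (adjusted p = 0.889). With limma voom Il1r2 (adjusted p = 0.142) and Cfb (0.0569) did not pass, and Siglec1 did not with the 12 libraries only (edgeR adjusted p = 0.0523) or against 1.2-fold (0.0562).

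Lists of structural and other cell types were tested after silica as well. Alveolar type 2 genes had 2 of 12 higher and 10 not passing (5 adjusted over the list alone), including Lamp3, a lamellar body protein, at 0.78 ± 0.17. The camera adjusted p was 2.01e-04, and adjusted p = 0.449 with an estimated correlation. Surfactant protein Sftpc stood at 0.18 ± 0.28 (adjusted p = 0.798). Endothelial markers had 0 of 11 passing (4 lower adjusted over the list alone), with camera adjusted p = 1.84e-06 downward and adjusted p = 0.157 with an estimated correlation, and Vwf stood at -0.34 ± 0.18. MHC class II genes had 1 of 8 higher and 7 not passing (3 adjusted over the list alone; camera adjusted p = 0.00111, and adjusted p = 0.367 with an estimated correlation). Proliferation genes had 0 of 12 passing (0 adjusted over the list alone), with camera adjusted p = 0.0118 upward and adjusted p = 0.458 with an estimated correlation. Extracellular matrix genes had 0 of 24 higher, 2 lower (1 without air 6) and 22 not passing (3 higher and 14 lower adjusted over the list alone), with camera adjusted p = 0.0210 downward and adjusted p = 0.486 with an estimated correlation. That call was lost without air 6 (0.247) and without silica 1 (0.0523), and the library air 6 held 480 CPM of Col1a1 against at most 119 CPM in the other air libraries. The collagen chain Col5a1 stood at -0.63 ± 0.16 (-0.33 without air 6, still passing), a call lost without silica 2 (adjusted p = 0.0761), silica 3 (0.0603), silica 5 (0.108) or silica 6 (0.0727). Tenascin C (Tnc) fell by 0.75 ± 0.21, a call lost without any single one of air 6, silica 2 to 6, smoke 5 and 6 or the 6 combined libraries (adjusted p up to 0.127). Alveolar type 1 markers had 0 of 9 passing (0 adjusted over the list alone), with camera adjusted p = 0.0429 and adjusted p = 0.486 with an estimated correlation. The call was lost without air 1, 2, 4 or 5, silica 2, 4 or 6, smoke 3 or combined 1, 2, 3 or 5 (0.0513 to 0.113). Collagen chain Col1a1 stood at -0.88 ± 0.36 (adjusted p = 0.175), fibronectin Fn1 at 0.09 ± 0.13, and the xenobiotic enzymes Cyp1b1 and Nqo1 at -0.61 ± 0.35 and -0.01 ± 0.15. Nqo1 was positive without air 2 (0.20), silica 4 (0.004) or silica 6 (0.02). Lcn2, a neutrophil and epithelial iron-binding protein, stood at 0.93 ± 0.42 (adjusted p = 0.224), and at 1.85 (adjusted p = 0.00542) without air 6. It passed with voom and quality weights (1.82, adjusted p = 0.00427) and without silica 1, smoke 1 and smoke 2 (1.12, edgeR 0.0407), as did Vwf without those 3 (-0.47, 2.98e-04). Lamp3 did not pass with limma voom (adjusted p = 0.0933) or against 1.2-fold (0.0803), nor did Col5a1 (0.0844 and 0.226) or Tnc (0.148 and 0.226). With 1 surrogate variable Col5a1 (0.126) and Tnc (0.0975) did not pass, nor with the 12 libraries only (0.127 and 0.159), and Tnc was at -0.39 (0.122) with quality weights. The call was lost with fry for the matrix and alveolar type 1 lists (adjusted p = 0.298 each), the alveolar type 2 list (0.195), the MHC class II list (0.0941) and the proliferation list (0.148).

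NRF2 antioxidant targets had 3 of 20 higher, 1 lower and 16 not passing after silica (4 and 1 adjusted over the list alone; camera adjusted p = 0.0770), with haem oxygenase Hmox1 at 1.13 ± 0.25 (adjusted p = 0.0554 without silica 6). Airway secretory genes had 1 of 11 higher (Chia), and circadian clock genes 1 of 15, the repressor Bhlhe41 at 0.98 ± 0.23 (adjusted p = 0.0702 without silica 5 and 0.0512 without silica 6). With limma voom Hmox1 (adjusted p = 0.0734) and Bhlhe41 (0.0569) did not pass, nor with the 12 libraries only (0.0604 and 0.1098), and Bhlhe41 did not against 1.2-fold (0.0757). Camera adjusted p was 0.315 and 0.432 for these lists. No member passed among aryl hydrocarbon receptor targets (5 tested, adjusted p = 0.407), ciliated cell genes (0.101), B and plasma cell markers (0.151), T and NK cell markers (0.801), interferon-stimulated genes (0.0784), cholesterol synthesis genes (0.101), cardiac muscle markers (0.315) or erythroid genes (0.948). In all, 287 genes were higher and 135 lower after silica of 13322 tested, and 815 and 799 of 13666 without silica 1, smoke 1 and smoke 2. The higher count was 716 without silica 1, 145 without silica 2, 133 without silica 3, 113 without silica 5 and 111 without silica 6. The lower count was 89 without air 1, 223 without air 5, 63 without air 6, 467 without silica 1, 35, 33, 71, 11 and 16 without silica 2, 3, 4, 5 and 6.

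Between smoke and air, the next comparison, 4 of 15 clock genes passed (n = 6 and 6), and the labels give no time of tissue collection. The clock repressor Nr1d1 (252917) rose by 2.49 ± 0.26 on the log2 scale (edgeR adjusted p = 1.85e-06), its relative Nr1d2 by 1.12 ± 0.14, Per3 by 1.11 ± 0.17 and the clock output factor Dbp (24309) by 1.49 ± 0.24. The clock activator Arntl stood at -0.45 ± 0.13 (adjusted p = 0.230), at -0.61 (adjusted p = 0.0269) without smoke 1, at -0.60 (0.0266) without silica 1, smoke 1 and smoke 2, and at -0.57 (0.0264) with voom and quality weights. The glucocorticoid-induced factors Zbtb16 (353227) and Tsc22d3 fell by 1.56 ± 0.23 and 0.96 ± 0.14, and in both every smoke library lay below every air library. Of 15 clock genes 4 were higher, 0 lower and 11 did not pass (6 higher and 2 lower adjusted over the list alone), with camera adjusted p = 3.56e-05 and adjusted p = 0.0388 with an estimated correlation. With fry the list was not called (adjusted p = 0.0682), and fry called 0 of the 22 lists for this comparison, against 9 by camera. Per3 did not pass with the 12 libraries only (adjusted p = 0.0580).

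The metalloprotease Adamts9 fell by 0.91 ± 0.18 with smoke, a call lost without air 3 (adjusted p = 0.0616), smoke 3 (0.0757), smoke 5 (0.0568) or smoke 6 (0.0585). Cd163, the macrophage haemoglobin scavenger receptor, fell by 1.19 ± 0.23 and was the 1 of 13 macrophage markers that passed (list adjusted p = 0.404), a call lost without air 3 (0.0616), air 4 (0.0831), air 5 (0.0636), smoke 3 (0.0551), smoke 4 (0.0771) or smoke 6 (0.0562). Haemoglobin genes Hbb and Hba1 were higher by 4.86 ± 1.01 and 4.27 ± 0.93, and stood at 0.55 (adjusted p = 0.621) and 0.39 (adjusted p = 0.766) without smoke 2, and at 0.67 (0.5261) and 0.55 (0.614) without the 3 libraries. Those calls were near the threshold. The Hbb call was lost also without air 1 to 5, silica 3 to 5 or combined 2 or 5 (adjusted p from 0.0510 to 0.127). The Hba1 call was lost without air 1 to 5, silica 2 to 6 or any combined library (0.0627 to 0.160). They were 2 of 6 erythroid genes (2 adjusted over the list alone), whose camera adjusted p of 1.48e-04 (adjusted p = 0.445 with an estimated correlation) became 0.462 without smoke 2. No neutrophil marker passed over all genes with edgeR (6 of 9 higher adjusted over the list alone), and the list was called upward (adjusted p = 5.80e-10, and adjusted p = 0.0388 with an estimated correlation, but 0.0682 with fry), with S100a9 at 1.52 ± 0.41 (adjusted p = 0.214, and 0.0413 without silica 1). Cytokines had 0 of 15 passing (2 adjusted over the list alone), with camera adjusted p = 5.25e-07 and adjusted p = 0.259 with an estimated correlation, and Ccl2 stood at 2.32 ± 0.63 (adjusted p = 0.214, and 0.0463 without silica 1). Without silica 1, smoke 1 and smoke 2, S100a9 stood at 0.70 and Ccl2 at 1.04. With limma voom Adamts9 and Cd163 (adjusted p = 0.0867 each), Hbb (0.277) and Hba1 (0.317) did not pass. With the 12 libraries only Adamts9 (0.134), Cd163 (0.0950), Hbb and Hba1 (0.4425 each) did not, nor against 1.2-fold (0.121, 0.0986, 0.0743 and 0.0986). With 1 surrogate variable Hbb stood at 0.59 (0.582) and Hba1 at 0.42 (0.725), with quality weights at 0.65 (0.713) and 0.44 (0.777), and with RLE scaling Hba1 had adjusted p = 0.05195.

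With smoke, Spp1 stood at 1.65 ± 0.80, Mmp12 at 1.43 ± 0.64 and Chi3l1 at 0.63 ± 0.25, none passing, and at 0.19, 0.06 and 0.19 without the 3 libraries. Xenobiotic and antioxidant genes did not pass: aryl hydrocarbon receptor targets had 0 of 5 (1 higher adjusted over the list alone, camera adjusted p = 0.260) and NRF2 targets 0 of 20 (0.882), with Cyp1b1 at 0.02 ± 0.33 and Nqo1 at 0.08 ± 0.15. Cyp1b1 was negative without any single one of air 1 to 3 or smoke 3, 4 or 6 (-0.15 to -0.02). Cyp1a1, the classical smoke-induced enzyme, was too low to test, at 0 CPM in smoke 1 and smoke 2 and 0.749, 1.49, 2.18 and 1.02 CPM in smoke 3 to 6. It was at 0 CPM in 4 air libraries, 0.375 CPM in air 5 and 29.9 CPM in air 6. Complement genes had 0 of 19 passing (0 adjusted over the list alone, camera adjusted p = 0.00186, adjusted p = 0.724 with an estimated correlation, 0.636 without smoke 1). Lipid-laden macrophage genes had 0 of 20 (0 adjusted over the list alone, 0.00813, adjusted p = 0.762 with an estimated correlation, 0.637 without air 6 and 0.426 without smoke 1). Cardiac muscle markers had 0 of 7 (0 adjusted over the list alone, 0.00813, adjusted p = 0.662 with an estimated correlation, 0.157 without air 5 and 0.205 without smoke 2). Matrix genes had 0 of 24 (0 adjusted over the list alone, 0.00813 downward, adjusted p = 0.734 with an estimated correlation), upward at 0.816 without air 6, and still downward but not called without smoke 2 (0.128). Alveolar type 2 genes had 0 of 12 (0 adjusted over the list alone, 0.0386 downward, adjusted p = 0.762 with an estimated correlation), upward at 0.931 without smoke 2, and 0.0833, 0.232, 0.0590 and 0.226 without air 1, 2, 4 and 5. Sftpc stood at -0.34 ± 0.28, Lcn2 at 0.46 ± 0.43 (-0.16 without smoke 1) and Col1a1 at -0.58 ± 0.36 (0.27 without air 6). No member passed and no list was called among airway secretory genes (1 of 11 higher adjusted over the list alone, camera adjusted p = 0.228), interferon-stimulated genes (0.228), alveolar type 1 markers (0.260), endothelial markers (0.343), MHC class II genes (0.404) or cholesterol genes (0.428). The same held for ciliated cell, B and plasma cell and proliferation genes (each 0.721) and T and NK cell markers (0.749).

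In all, 13 genes were higher and 7 lower with smoke, and 13 and 10 without the 3 libraries. The higher count was 4 without air 3, 5 without air 4 or air 5, 25 without silica 1, 7 without silica 4 or silica 5 and 8 without smoke 3. The lower count was 28 without air 6 and 13 without silica 1. It was 2 without air 3 or smoke 3, 3 without air 4, air 5 or smoke 6, and 4 without silica 4, silica 5, smoke 5 or combined 5.

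**Figure D2:**
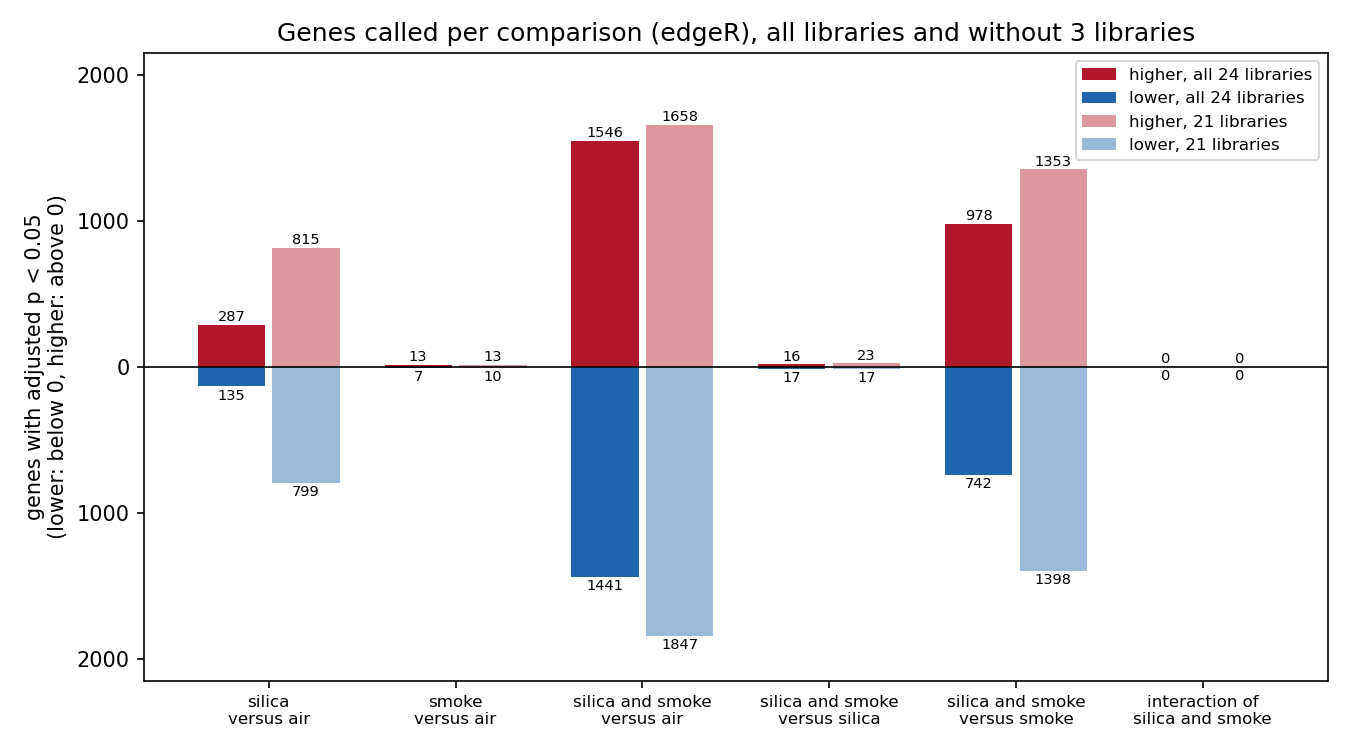
Number of genes higher and lower in each comparison (edgeR, adjusted p under 0.05), with all 24 libraries and with the 21 left without silica 1, smoke 1 and smoke 2. The combined group against air had the most, 1546 higher and 1441 lower, and the interaction had 0.

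Against air, the combined group showed the widest change (n = 6 and 6). Spp1 rose by 5.64 ± 0.56 on the log2 scale (edgeR adjusted p = 1.16e-07), Ccl2 by 4.59 ± 0.50, Ccl7 by 4.41 ± 0.47, Mmp12 by 3.74 ± 0.53 and Chia by 3.85 ± 0.38. Lactoperoxidase (Lpo, 287610), an antimicrobial airway enzyme, rose from 0.0341 ± 0.0836 CPM, with a count in 1 air library, to 77.3 ± 12.4 CPM (SD). Retnla, a marker of alternatively activated macrophages, rose by 4.63 ± 0.55, the acute phase protein Orm1 by 5.00 ± 0.67 and the anion exchanger Slc26a4 by 4.46 ± 0.57. Zbtb16 fell by 1.90 ± 0.23. The natriuretic peptide clearance receptor Npr3 fell by 1.90 ± 0.25 and Adamts9 by 1.40 ± 0.17. Dlk1 fell by 3.22 ± 0.84, and stood at 0.35 (adjusted p = 0.948) with 1 surrogate variable in the model. With limma voom Dlk1 (adjusted p = 0.0891) and Lpo (0.0512) did not pass.

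Camera called 13 of 22 lists in the combined group against air with the preset correlation and 0 with an estimated one. Complement genes had 17 of 19 higher and 2 not passing (19 adjusted over the list alone; camera adjusted p = 3.45e-20, and adjusted p = 0.0670 with an estimated correlation). They included Cfi at 3.56 ± 0.39, Ptx3 at 2.37 ± 0.31, Hp at 1.94 ± 0.23 and Cfb at 1.67 ± 0.22. Lipid-laden macrophage genes had 17 of 20 higher and 3 not passing (18 higher and 1 lower adjusted over the list alone), with camera adjusted p = 7.64e-17 and adjusted p = 0.0959 with an estimated correlation. Among them Fabp4 rose by 2.78 ± 0.26, Chi3l1 by 2.23 ± 0.25 and the protease Ctsk by 1.66 ± 0.25. Cytokines had 9 of 15 higher, 1 lower and 5 not passing (11 and 1 adjusted over the list alone), with Il1rn, the interleukin 1 antagonist, at 1.75 ± 0.25. Neutrophil markers had 6 of 9 higher and 3 not passing (6 adjusted over the list alone), with S100a9 at 3.35 ± 0.40. Macrophage markers had 8 of 13 higher, 1 lower and 4 not passing (8 and 2 adjusted over the list alone): Siglec1 rose by 1.47 ± 0.18 and the signalling adaptor Tyrobp by 0.87 ± 0.14, and Cd163 fell by 1.33 ± 0.23. Camera adjusted p was 8.09e-08, 3.94e-06 and 2.32e-05 for these lists, with adjusted p = 0.117, 0.117 and 0.126 with an estimated correlation. MHC class II genes had 7 of 8 higher and 1 not passing (7 adjusted over the list alone; 3.94e-06, and adjusted p = 0.117 with an estimated correlation). RT1-Ba stood at 0.73 ± 0.12 and RT1-Da at 0.82 ± 0.15.

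Metabolic and structural lists split in the combined group. NRF2 targets had 9 of 20 higher, 2 lower and 9 not passing (9 and 2 adjusted over the list alone; camera adjusted p = 3.50e-04, and adjusted p = 0.222 with an estimated correlation). Among them were the cystine transporter Slc7a11 at 2.28 ± 0.36, Hmox1 at 1.62 ± 0.23 and Prdx1 at 0.58 ± 0.10. Cholesterol synthesis genes had 8 of 11 higher and 3 not passing (10 adjusted over the list alone; 2.10e-06, and adjusted p = 0.0959 with an estimated correlation). Insig1 stood at 0.50 ± 0.09. Alveolar type 2 genes had 6 of 12 higher and 6 not passing (6 adjusted over the list alone; 1.79e-05, and adjusted p = 0.235 with an estimated correlation). Surfactant protein Sftpd rose by 1.19 ± 0.19, the surfactant lipid enzyme Lpcat1 by 0.84 ± 0.14 and the protease Napsa by 0.87 ± 0.15. Proliferation genes had 5 of 12 higher and 7 not passing (5 adjusted over the list alone; 0.00125, and adjusted p = 0.235 with an estimated correlation), with Mcm5 at 1.41 ± 0.30 and Rrm2 at 1.57 ± 0.35. Endothelial markers had 0 of 11 higher, 8 lower and 3 not passing (8 adjusted over the list alone; 2.10e-06, and adjusted p = 0.117 with an estimated correlation). The tight junction gene Cldn5 fell by 0.82 ± 0.13, Plvap by 0.66 ± 0.16 and Pecam1 by 0.41 ± 0.09. Alveolar type 1 markers had 1 of 9 higher, 4 lower and 4 not passing (1 and 4 adjusted over the list alone; 0.00278, and adjusted p = 0.303 with an estimated correlation). Rtkn2 fell by 0.59 ± 0.13 and Pdpn by 0.48 ± 0.12. With limma voom Plvap (adjusted p = 0.0578) and Rtkn2 (0.0730) did not pass, and against 1.2-fold Pecam1 (0.126) and Pdpn (0.106) did not.

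Ciliated cell genes had 1 of 12 higher, 5 lower and 6 not passing in the combined group (1 and 5 adjusted over the list alone; camera adjusted p = 0.0362 downward, and adjusted p = 0.4655 with an estimated correlation). The call was lost without air 3 (0.103), air 6 (0.0527), combined 2 (0.114) or combined 6 (0.0640). The cilium regulator Foxj1 fell by 0.54 ± 0.16 and Dnai1 by 0.71 ± 0.20, and Tekt2 rose by 0.71 ± 0.15. With 1 surrogate variable Foxj1 stood at -0.23 (adjusted p = 0.905) and Dnai1 at -0.38 (0.478), and neither passed with DESeq2 (0.0629 and 0.0699) or against 1.2-fold (0.103 and 0.0575). With fry the list had adjusted p = 0.0542. Clock genes had 7 of 15 higher, 5 lower and 3 not passing (7 and 7 adjusted over the list alone; 0.176), with Dbp at 2.08 ± 0.22, Nr1d1 at 2.25 ± 0.26 and Arntl at -0.93 ± 0.13. Matrix genes had 3 of 24 higher, 6 lower and 15 not passing (4 and 9 adjusted over the list alone; 0.377): Mmp14 rose by 0.72 ± 0.14 and elastin (Eln) fell by 1.09 ± 0.22. Without air 6, Eln stood at -0.70 and still passed, and 4 members were higher and 2 lower. Col1a1 fell by 0.98 ± 0.35 (adjusted p = 0.0453), and stood at -0.13 (0.698) without air 6. It did not pass with DESeq2 (-0.93, adjusted p = 0.141), limma voom (-0.37, 0.449), quality weights (-0.15, 0.693), the 12 libraries only (-0.98, 0.118), 1 surrogate variable (-0.58, 0.553) or against 1.2-fold (0.126). Its call was lost also without silica 2 to 6, smoke 3, 5 or 6 or combined 1, 2, 3, 5 or 6 (0.0515 to 0.0947). Airway secretory genes had 2 of 11 higher and 2 lower (0.244), B and plasma cell markers 2 of 9 higher (0.738), with Mzb1 at 1.05 ± 0.25 (DESeq2 adjusted p = 0.0808), T and NK cell markers 2 of 16 higher (0.711) and interferon-stimulated genes 2 of 16 higher (0.574). Cardiac muscle markers (0.244), erythroid genes (0.551) and aryl hydrocarbon receptor targets (0.711) had no member that passed. Lcn2 stood at 0.92 ± 0.41 (adjusted p = 0.102), and at 1.85 (3.57e-04) without air 6. It passed with limma voom (1.36, adjusted p = 0.0356) and with quality weights (1.75, 4.60e-04). Nqo1 stood at 0.30 ± 0.15 (adjusted p = 0.144), and at 0.52 (6.41e-04) without air 2, where it was at 67.0 CPM. Cyp1b1 stood at -0.51 ± 0.33, Fn1 at 0.10 ± 0.13 and Sftpc at 0.19 ± 0.28. In all, 1546 genes were higher and 1441 lower, and 1658 and 1847 without silica 1, smoke 1 and smoke 2.

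Clock genes also differed between the combined group and silica, where 7 of 15 passed (n = 6 and 6). Dbp rose from 5.50 ± 2.39 to 24.9 ± 4.50 CPM (SD), a log2 fold change of 2.03 ± 0.24 (edgeR adjusted p = 2.65e-05). Nr1d1 rose by 1.54 ± 0.26, Per3 by 1.16 ± 0.18 and Nr1d2 by 0.95 ± 0.14, and Arntl and its partner Npas2 fell by 0.86 ± 0.13 and 0.79 ± 0.15. Zbtb16 fell by 1.54 ± 0.24, Npr3 fell by 1.501 ± 0.251 and the phosphodiesterase Pde3a by 0.72 ± 0.14. The epithelial oxidase Duox1 rose by 1.15 ± 0.19 and the collagen Col16a1 by 0.94 ± 0.16.

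Clock genes had 5 of 15 higher, 2 lower and 8 not passing (6 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00157, and adjusted p = 0.167 with an estimated correlation). Cholesterol genes had 1 of 11 higher and 10 not passing (7 adjusted over the list alone; 1.36e-08, and adjusted p = 0.0964 with an estimated correlation). Complement genes had 0 of 19 passing over all genes (11 adjusted over the list alone), with camera adjusted p = 4.46e-10 upward and adjusted p = 0.190 with an estimated correlation. Lipid-laden macrophage genes (0 of 20 passing, 4 adjusted over the list alone, camera adjusted p = 4.88e-08), NRF2 targets (0 of 20, 1 adjusted over the list alone, 3.64e-04) and MHC class II genes (0 of 8, 0 adjusted over the list alone, 2.68e-04) were called upward. Each had adjusted p = 0.264 with an estimated correlation. A further 6 lists were called with the preset correlation and lost the call without at least 1 library. The macrophage list (0.0333, 3 of 13 higher and 2 lower adjusted over the list alone) was lost without silica 1 (0.201), silica 2 (0.0761) or combined 6 (0.0695), and the endothelial list (0.0208, downward) without silica 1 (0.209) or combined 6 (0.0557). The alveolar type 2 list (0.00596) was lost without silica 1 (0.0797), and the alveolar type 1 list (0.0202 downward, 1 of 9 lower adjusted over the list alone) without silica 1 (0.0505) or silica 3 (0.0546). The B and plasma cell list (0.0344, 1 of 9 higher adjusted over the list alone) was lost without silica 3 (0.0546), silica 4 (0.0888), silica 5 (0.0736), silica 6 (0.0513), combined 1 (0.129) or combined 5 (0.0625). The proliferation list (0.0333, 1 of 12 higher adjusted over the list alone) was lost without silica 1 (0.162), silica 3 (0.0546), silica 6 (0.0513), combined 3 (0.0667) or combined 4 (0.0810). With an estimated correlation their adjusted p was 0.326 for B and plasma cells and 0.465 for the other 5. With fry the clock and cholesterol lists kept the call and the other 10 lost it (adjusted p from 0.0648 to 0.380). Against 1.2-fold Npas2 and Pde3a did not pass (edgeR adjusted p = 0.144 each).

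Several genes that passed in silica against air did not pass here: Spp1 at 1.25 ± 0.39 (adjusted p = 0.166), Ccl2 at 0.84 ± 0.36, Mmp12 at 0.74 ± 0.43, C3 at 0.53 ± 0.27 and Chi3l1 at 0.67 ± 0.24 (adjusted p = 0.221, and 0.0437 at 0.47 without the 3 libraries). Cyp1b1 stood at 0.10 ± 0.38, Nqo1 at 0.31 ± 0.15, Lcn2 at -0.01 ± 0.41, Sftpc at 0.01 ± 0.28 and Col1a1 at -0.09 ± 0.38. Cyp1b1 was negative without silica 3 (-0.02) or combined 4 (-0.04), Sftpc without silica 1 (-0.09), combined 3 (-0.01) or combined 4 (-0.05), and Lcn2 positive without any single one of silica 2, 3 or 6 or combined 3 to 6 (0.01 to 0.13). Lists not called and with no member passing were aryl hydrocarbon receptor targets (1 of 5 higher adjusted over the list alone, camera adjusted p = 0.126), ciliated cell genes (0.143), erythroid genes (0.283) and matrix genes (0.299). Airway secretory genes (3 higher and 1 lower adjusted over the list alone, 0.299), interferon-stimulated genes (0.299), cardiac muscle markers (0.380), cytokines (2 and 2 adjusted over the list alone, 0.615), neutrophil markers (0.738) and T and NK cell markers (0.779) were likewise not called. In all, 16 genes were higher and 17 lower, and 23 and 17 without the 3 libraries. The higher count was 56 without air 6, 31 without silica 3, 26 without smoke 1 or combined 4, and 9 without silica 1, combined 3 or combined 6. The lower count was 57 without air 6, 30 without smoke 2, 26 without silica 4, 7 without silica 1, 10 without combined 6, and 11 without silica 5 or combined 2, 3 or 5.

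Silica was also compared on top of smoke, in the combined group against smoke (n = 6 and 6), whose smoke in week 1 also differed per the labels (45 and 40 mg/m3). Spp1 rose by 3.99 ± 0.51 on the log2 scale (edgeR adjusted p = 2.95e-05), Retnla by 3.69 ± 0.55, Ccl7 by 2.56 ± 0.41, Mmp12 by 2.31 ± 0.49, Ccl2 by 2.26 ± 0.42, Fabp4 by 2.33 ± 0.27 and Chi3l1 by 1.60 ± 0.25. Without silica 1, smoke 1 and smoke 2, Spp1 was 5.43, Retnla 5.49, Ccl7 3.64, Mmp12 3.67, Ccl2 3.54 and Cfi 3.295. Complement genes had 15 of 19 higher and 4 not passing (16 adjusted over the list alone; camera adjusted p = 1.36e-17, and adjusted p = 0.0339 with an estimated correlation). Cfi stood at 2.46 ± 0.37, Hp at 1.45 ± 0.24, Cfb at 1.36 ± 0.23 and C1s at 0.75 ± 0.12. Cholesterol genes had 10 of 11 higher and 1 not passing (10 adjusted over the list alone; 3.18e-09, and adjusted p = 0.0339 with an estimated correlation), with Cyp51 at 0.85 ± 0.15 and Idi1 at 0.81 ± 0.18.

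Lipid-laden macrophage genes had 15 of 20 higher and 5 not passing (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.09e-15, and adjusted p = 0.0917 with an estimated correlation). Alveolar type 2 genes had 6 of 12 higher and 6 not passing (8 adjusted over the list alone; 6.12e-11, and adjusted p = 0.108 with an estimated correlation). Sftpd stood at 1.11 ± 0.20 and Lpcat1 at 0.81 ± 0.15. Macrophage markers had 8 of 13 higher and 5 not passing (9 adjusted over the list alone; 3.07e-05, and adjusted p = 0.149 with an estimated correlation), with Siglec1 at 1.01 ± 0.18. MHC class II genes had 4 of 8 higher and 4 not passing (6 adjusted over the list alone; 3.05e-06, and adjusted p = 0.137 with an estimated correlation). RT1-Ba stood at 0.65 ± 0.12 and the invariant chain Cd74 at 0.71 ± 0.15. NRF2 targets had 9 of 20 higher and 11 not passing (9 adjusted over the list alone; 8.11e-05, and adjusted p = 0.160 with an estimated correlation). Hmox1 stood at 1.15 ± 0.24 and Prdx1 at 0.69 ± 0.10. Proliferation genes had 7 of 12 higher and 5 not passing (10 adjusted over the list alone; 9.50e-05, and adjusted p = 0.160 with an estimated correlation). Of these Rrm2 rose by 2.04 ± 0.40, Mcm2 by 0.81 ± 0.19 and Mki67 by 1.08 ± 0.29 (adjusted p = 0.0568 without smoke 3, 0.0525 with DESeq2 and 0.0697 against 1.2-fold). Cytokines had 5 of 15 higher, 1 lower and 9 not passing (7 and 1 adjusted over the list alone; 9.23e-04, and adjusted p = 0.269 with an estimated correlation).

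Endothelial markers had 0 of 11 higher, 7 lower and 4 not passing when silica was added to smoke (10 lower adjusted over the list alone; camera adjusted p = 1.45e-06, and adjusted p = 0.149 with an estimated correlation). With fry the alveolar type 1 (adjusted p = 0.193), ciliated cell (0.0994) and erythroid lists (0.119) lost the call. The endothelin receptor Ednrb fell by 0.54 ± 0.11, the capillary enzyme Car4 by 0.47 ± 0.11 and Pecam1 by 0.40 ± 0.09. Alveolar type 1 markers had 4 of 9 lower and 5 not passing (4 adjusted over the list alone; 0.00806, and adjusted p = 0.370 with an estimated correlation; 0.0513 without smoke 3), with Rtkn2 down by 0.58 ± 0.14. Ciliated cell genes had 1 of 12 higher, 3 lower and 8 not passing (1 and 5 adjusted over the list alone; 0.00668, and adjusted p = 0.342 with an estimated correlation). Cardiac muscle markers had 0 of 7 passing (0 adjusted over the list alone; 0.00131 downward, and adjusted p = 0.269 with an estimated correlation). Haemoglobin Hbb and Hba1 were lower by -4.79 ± 1.01 and -4.34 ± 0.93, and stood at -0.47 (adjusted p = 0.309) and -0.45 (0.329) without smoke 2. The erythroid list (2 of 6 lower, 3 adjusted over the list alone, 0.00181, and adjusted p = 0.303 with an estimated correlation) stood at 0.0785 without smoke 2. Albumin (Alb) was lower by -5.61 ± 1.44, and stood at -3.59 (adjusted p = 0.137) without smoke 1. It did not pass with limma voom (-3.70, adjusted p = 0.284), quality weights (-3.30, 0.116) or without the 3 libraries (-2.94, 0.175). With 1 surrogate variable Car4 (-0.36, 0.0885), Hbb (-0.71, 0.163) and Hba1 (-0.67, 0.167) did not pass, and with quality weights Hbb was -0.68 (0.351) and Hba1 -0.55 (0.349). With limma voom Rtkn2 was -0.47 (0.177). Against 1.2-fold Ednrb (0.0739), Car4 (0.157), Pecam1 (0.255) and Rtkn2 (0.0824) did not pass.

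Among the remaining lists in the combined group against smoke, matrix genes had 3 of 24 higher (camera adjusted p = 0.701), neutrophil markers 2 of 9 higher (0.112) and airway secretory genes 2 of 11 higher and 1 lower (0.530). B and plasma cell markers had 1 of 9 higher (0.948) and clock genes 1 of 15 higher, Bhlhe41 at 0.97 ± 0.22, and 2 lower (0.514). Aryl hydrocarbon receptor targets had 1 of 5 lower, the aldehyde dehydrogenase Aldh3a1 at -1.29 ± 0.36 (list 0.845). Aldh3a1 stood at -0.32 (adjusted p = 0.881) with 1 surrogate variable and did not pass against 1.2-fold (0.0693). T and NK cell markers (0.913) and interferon-stimulated genes (0.913) had no member that passed. Sftpc stood at 0.53 ± 0.28 (passing with limma voom at 2.04, adjusted p = 0.0345, and without the 3 libraries at 0.36, edgeR 0.0440), Lcn2 at 0.46 ± 0.42 (passing with quality weights at 0.96, 0.0276), Nqo1 at 0.22 ± 0.15, Cyp1b1 at -0.53 ± 0.36 and Col1a1 at -0.39 ± 0.38. In all, 978 genes were higher and 742 lower, and 1353 and 1398 without silica 1, smoke 1 and smoke 2. The higher count was 581 without smoke 3 and 586 without smoke 4. The lower count was 324 without smoke 3, 389 without smoke 4, 441 without smoke 6, 493 without combined 2, 488 without combined 3 and 486 without combined 6.

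The interaction asked whether both exposures together gave more or less than the sum of each on the log2 scale, which is the product of their fold changes. A sum of changes in CPM was not tested. Smoke in week 1 was 45 mg/m3 in the combined group and 40 mg/m3 in the smoke group per the labels, so the term also holds that difference. With edgeR 0 genes passed, 977 had an unadjusted p under 0.05, and limma voom called 0, DESeq2 1 lower (Alb, log2 -10.85, adjusted p = 1.90e-04) and voom with library quality weights 3 higher and 6 lower. Without the 3 libraries 0 passed and 1205 had an unadjusted p under 0.05. The 5 genes with the smallest p were the growth-factor-response gene Klf10 at -0.77 ± 0.16 (adjusted p = 0.178), Spry4 at -0.91 ± 0.19, Ppil1 at 0.95 ± 0.20, Alb at -7.84 ± 1.66 and the transcription factor Prdm1 at -0.84 ± 0.19 (adjusted p = 0.214). Klf10, Ppil1 and Prdm1 passed with quality weights (-0.80, 0.81 and -0.89, adjusted p = 0.0398 each). The always-named genes did not pass: Ccl2 at -1.49 ± 0.74, Mmp12 at -0.68 ± 0.77, Spp1 at -0.39 ± 0.88, Lcn2 at -0.46 ± 0.59, Chi3l1 at 0.03 ± 0.35, Cyp1b1 at 0.08 ± 0.50, Nqo1 at 0.24 ± 0.22, Sftpc at 0.35 ± 0.39 and Col1a1 at 0.49 ± 0.52. Without smoke 1, Spp1 stood at 1.07, Mmp12 at 0.69 and Lcn2 at 0.16, and without air 6 Col1a1 stood at -0.37. Chi3l1 was negative without any single one of air 5 or 6, silica 1, smoke 3, 4 or 6 or combined 3 (-0.16 to -0.01), and Cyp1b1 without any single one of air 5 or 6, silica 2 or 3, smoke 1 or combined 4 (-0.12 to -0.01).

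Camera called 13 of 22 lists for the interaction with the preset correlation and 0 with an estimated one, where the lowest was adjusted p = 0.104, that of cholesterol synthesis genes, and fry called 1, the same list (adjusted p = 0.0445, and 0.0999 without the 3 libraries). No list member passed over all genes. Cholesterol genes (6 of 11 higher adjusted over the list alone, camera adjusted p = 1.33e-07) and alveolar type 2 genes (0 of 12, 5.62e-05) were called upward whichever library was left out. Neutrophil markers (0 of 9, 1.29e-05) and erythroid genes (4 of 6 lower adjusted over the list alone, 1.29e-05, and 0.202 without the 3 libraries) were called downward. With an estimated correlation these 4 lists had adjusted p = 0.104, 0.503, 0.318 and 0.345. The remaining 9 lists each lost the call without at least 1 library and are not described.

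Response scores summarised each library on genes chosen from the same libraries. Over 132 silica-response genes (120 higher, 12 lower) the score was 1.27 ± 0.70 in silica, -0.02 ± 1.08 in smoke and 1.91 ± 0.14 in the combined group (SD, n = 6 each, air mean at 0). The combined group exceeded silica by 0.64 (two-sided exact permutation p = 0.0022, the smallest that 6 against 6 can give), smoke against air gave p = 0.974 by the same exact test, and the interaction was 0.66 (permutation p = 0.275). With genes of at least 1.5-fold these differences were 0.37 and 0.41. Without the 3 libraries, over 230 genes, the means were 1.28 ± 0.11 (n = 5), 0.04 ± 0.05 (n = 4) and 1.60 ± 0.13 (n = 6), a difference of 0.32 (exact permutation p = 0.00433) and an interaction of 0.28 (permutation p = 0.0294). Over 13 smoke-response genes the score was 1.13 ± 0.51 in silica (exact permutation p = 0.00433 against air), 1.201 ± 0.265 in smoke and 2.36 ± 0.08 in the combined group (SD, n = 6 each). The combined group exceeded smoke by 1.16 (exact permutation p = 0.0022) and the interaction was 0.03 (permutation p = 0.931). With genes chosen without the animal scored, that excess was 1.76 and the interaction 0.69 (permutation p = 0.0608). With the median over score genes, silica stood at 0.4999 (exact permutation p = 0.00649) and the interaction at 0.43 (permutation p = 0.113), and with genes of at least 1.5-fold the excess was 0.66 and silica 0.70. Without the 3 libraries, over 9 genes, silica stood at 0.07 ± 0.33 (n = 5, exact permutation p = 0.643), smoke at 1.34 ± 0.08 (n = 4) and the combined group at 1.61 ± 0.04 (n = 6). The excess over smoke was then 0.27 (exact permutation p = 0.00476) and the interaction 0.19 (permutation p = 0.235).

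Across 13322 genes, which are not independent replicates, the log2 fold changes of silica without smoke and with smoke had a Pearson r of 0.540, and 0.633 without the 3 libraries. These comparisons share no library. Of their calls 213 genes were higher in both, where 21.1 would be shared by independent lists, 56 were lower in both (7.52) and 0 were opposite. Without the 3 libraries 610 were higher in both (80.7), 483 lower in both (81.7) and 1 was opposite. For smoke without and with silica r was 0.157, 0.0343 without smoke 1 alone, and 0.0378 without the 3 libraries. Calls shared in both numbered 4 higher (0.0156 by independent lists) and 1 lower (0.00893), and 5 (0.0219) and 4 (0.0124) without the 3 libraries.

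**Figure D3:**
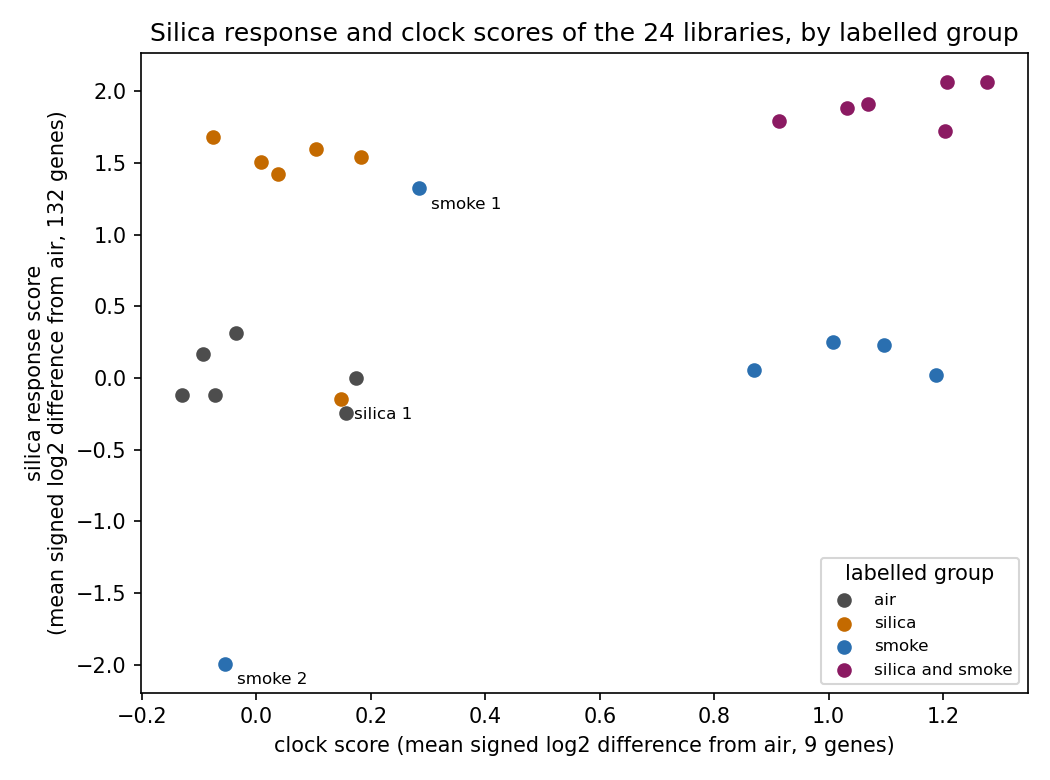
Silica response score against clock score (both log2 differences from the air mean) for the 24 libraries, coloured by group, with silica 1, smoke 1 and smoke 2 named. Clock scores ran from -0.13 to 0.18 in air and the other silica libraries and from 0.87 to 1.28 in smoke 3 to 6 and the combined libraries. The clock genes were chosen for a smoke effect in these libraries, so the gap between the ranges is partly by choice.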

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

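The always-named genes and the response scores were fixed in advance. The other measures and the tests of explanations in this part were chosen after the result was seen, with the prediction on exchanged labels written before its test was run. A library was picked out when its gap to the nearest other library of its group was a large share of the group's range. Of 60 groups checked over 15 measures, 19 had such a library, from 8 libraries, and chance flags about 1 in 20 groups.

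The macrophage genes Mmp12 and Chi3l1 stood apart in the libraries labelled silica 1 (3.26 and 123 CPM, both low for silica) and smoke 1 (57.9 and 401 CPM, both high for smoke). Spp1 was at 33.5 CPM in smoke 1. Silica 1 also stood apart in its silica response score (-0.14), smoke response score (0.11), Sftpc (4435 CPM) and Cyp1a1 (0.4662 CPM, which is 1 count, with 0 in the other 5 silica libraries). In air libraries the genes that stood apart were Cyp1a1 at 29.9 CPM, Lcn2 at 68.3 CPM and Col1a1 at 480 CPM in air 6, and Nqo1 at 67.0 CPM in air 2. In the combined group, Cyp1a1 was at 2.77 CPM in combined 4 and Chi3l1 at 698 CPM in combined 3. Low depth went with 13635 genes counted in silica 4 and 3469 in smoke 2, where Sftpc was at 370 CPM and haemoglobin took 56.0% of counts.

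Silica-response genes were low in the library labelled silica 1 and high in the one labelled smoke 1. An exchange of these labels was argued against by a clock score of 0.15 in silica 1, where smoke 3 to 6 and the combined libraries began at 0.87, and low depth by the lower total of the 2 libraries, 0.919 times the median. For smoke 1, an inflamed lung in a smoke-exposed animal stays open. Its clock score of 0.28 argued against it, below 0.87 by 0.59 where air libraries spanned 0.304. The clock genes were chosen on the libraries that set the 0.87, so a library left out of that choice may score lower. The time of collection was not tested. Zbtb16 did not argue against an inflamed lung, at 77.98 CPM in smoke 1 and 38.18 to 95.36 CPM in smoke 3 to 6. Air libraries had at least 138 CPM of Zbtb16 and silica libraries at least 100.9 CPM. That gene was picked by hand, and smoke 1 had taken part in choosing it. The score of 20 other smoke genes in smoke 1, at 0.12, lay below the smoke range by 0.29, within the air span of 0.332, and decided nothing. A wrong label on smoke 1 alone stays open, and its clock score lay above air and the other silica libraries (at most 0.18). An animal that responded unlike its group stays open for silica 1. A wrong label on silica 1 alone was not tested and stays open too. Its silica response score of -0.14 lay within the range of the air libraries (-0.25 to 0.31).

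Haemoglobin genes dominated smoke 2. A lung library that differed only in depth was argued against by the haemoglobin share of 56.0%. RNA from blood in place of lung predicted few alveolar transcripts, and Sftpc, Sftpb and Ager took 0.136% of the counts without haemoglobin (exact binomial interval 0.0727% to 0.233%), 0.129 times the median of the other libraries. How blood RNA came to dominate was not tested, and no biological explanation was tested.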

How the results depend on the processing

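Voom with library quality weights, the analysis without silica 1, smoke 1 and smoke 2, and leaving out each library for lists and for agreement across genes were tests chosen after the result was seen. Over the alternatives and left-out libraries, values of named genes kept direction and side of the threshold in 6022 cases, lost the call in 166, gained it in 21 and reversed in 59, and lists kept it in 2133, lost it in 227 and reversed in 3. Apart from the always-named ones, these genes were picked partly after their stability had been seen. Gene values that were not called and stayed so also count as kept. Of the kept cases, 4194 for genes and 1639 for lists came from leaving out 1 library, and those fits share most libraries. The kept cases include 180 for genes and 72 for lists from the filter at 1 CPM, whose outcome was fixed since it could remove no kept gene. Scaling by RLE or upper quartile left every count of called genes within 1.5 times. Stricter thresholds lower counts by construction. Leaving libraries out lowered some counts and raised others, and for these and the other changes below the cause was not tested. Depth limits low genes in smoke 2 and silica 4.

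Counts are given as higher and lower. Silica against air gave 148 and 41 with DESeq2, 83 and 21 with voom, 577 and 332 with voom and quality weights, 80 and 11 with its 12 libraries, 8 lower with 1 surrogate variable, 78 and 0 tested against 1.2-fold, 50 lower at 1.5-fold or more, 79 and 5 at adjusted p under 0.01, and 815 and 799 without the 3 libraries. Smoke against air gave 5 and 2 with voom, 28 and 44 with weights, 3 and 2 with its 12 libraries, 8 higher with 1 surrogate variable, 5 and 2 against 1.2-fold and 4 and 2 under 0.01. The combined group against air gave 856 and 809 with DESeq2, 493 lower with 1 surrogate variable, 668 and 430 against 1.2-fold, 754 and 539 at 1.5-fold and 920 and 708 under 0.01. Against silica it gave 57 and 59 with weights, 47 and 53 with its 12 libraries, 6 and 3 against 1.2-fold, 11 lower at 1.5-fold and 9 and 8 under 0.01. Against smoke it gave 445 and 378 with DESeq2, 1765 and 1603 with weights, 180 lower with 1 surrogate variable, 255 and 67 against 1.2-fold, 482 and 236 at 1.5-fold, 413 and 216 under 0.01 and 1398 lower without the 3 libraries. The interaction gave 1 lower with DESeq2 and 3 higher and 6 lower with weights.

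Of the results that reversed under these alternatives, Dlk1 and the alveolar type 2 list were called in the model used for the report and the others were not. With silica against air they were Col1a1 0.00306 with weights and Cyp1b1 0.0533 with 1 surrogate variable. In smoke against air they were Col1a1 0.29 with weights, Cyp1b1 -0.0742 and the alveolar type 2 list (adjusted p = 0.963) with 1 surrogate variable, and Lcn2 -0.17 without the 3 libraries. In the combined group against air, 1 surrogate variable gave Dlk1 0.35 and Cyp1b1 0.39. Against silica, Lcn2 was 0.0301 with DESeq2 and 0.12 with voom, and Sftpc -0.0385 with weights, -0.0271 with 1 surrogate variable and -0.0966 without the 3 libraries. Against smoke, 1 surrogate variable gave Cyp1b1 0.46 and Col1a1 0.0155. In the interaction Spp1 was 0.46 with voom and 0.77 without the 3 libraries, where Mmp12 was 0.39, and weights gave Cyp1b1 -0.21 and Col1a1 -0.44. Without the 3 libraries the silica score in smoke against air was 0.0442 (exact permutation p = 0.638), its interaction 0.28 (permutation p = 0.0294), the smoke score in silica 0.0711 (exact permutation p = 0.643), and r was 0.633 for silica and 0.0378 for smoke. With score genes of 1.5-fold or more the smoke score interaction was -0.0391.

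Leaving out each of the 24 libraries, counts of higher genes ran from 111 to 716 and of lower genes from 11 to 467 for silica against air. They ran from 4 to 25 and 2 to 28 for smoke against air and 1227 to 1682 and 1124 to 1588 for combined against air. For the combined group they ran from 9 to 56 and 7 to 57 against silica and 581 to 1263 and 324 to 1051 against smoke. The interaction stayed at 0 with edgeR (977 at an unadjusted p under 0.05 with all libraries, DESeq2 1, voom 0). The r ran from 0.497 to 0.594 for silica and 0.0343 to 0.188 for smoke. Log2 values that reversed ran, for silica against air, from -0.0764 to 0.20 (Nqo1), and for smoke against air from -0.15 to 0.22 (Cyp1b1), -0.77 to 0.27 (Col1a1) and -0.16 to 1.39 (Lcn2). List adjusted p in smoke against air ran from 7.85e-04 to 0.816 (matrix) and 6.79e-04 to 0.931 (alveolar type 2). Against silica the combined group ran from -0.0949 to 0.0628 (Sftpc), -0.23 to 0.13 (Lcn2) and -0.0357 to 0.34 (Cyp1b1). Interaction values ran from -0.12 to 0.33 (Cyp1b1), -0.16 to 0.47 (Chi3l1), -0.37 to 0.68 (Col1a1), -0.77 to 1.07 (Spp1), -1.40 to 0.16 (Lcn2) and -1.20 to 0.69 (Mmp12).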

Other observations

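The tests in this part on clock genes were chosen after the result was seen, and those on glucocorticoid-responsive genes and on other splits of the libraries were written before they were run. The lower Zbtb16 and Tsc22d3 of the report led to a list of other genes induced by glucocorticoid hormone, tested as the smoke effect averaged over air and silica backgrounds. The cell cycle inhibitor Cdkn1a fell by 0.40 ± 0.08 on the log2 scale (edgeR adjusted p = 0.0121, and 0.0259 without silica 1, smoke 1 and smoke 2), and the receptor chaperone Fkbp5 fell by 0.48 ± 0.12 (0.0456, and 0.109 without them). The kinase gene Sgk1 stood at 0.10 ± 0.08, Ddit4 at -0.68 ± 0.26 and Klf9 at -0.27 ± 0.08, none passing. Over 9 such genes camera gave p = 3.87e-06 downward, and p = 0.0159 with an estimated correlation (1.32e-05 and 0.0302 without the 3 libraries). Mt2A was on the list too but was not among the tested genes. A lower glucocorticoid response in smoke-exposed animals was the hypothesis, and the direction it predicted was found, on the same libraries that raised it. Tsc22d3 was low with silica too, at 149.2 to 220.6 CPM in silica 2 to 6 against at least 233.2 CPM in air. The combined libraries had 143.7 to 198.1 CPM. Zbtb16 in silica 2 to 6 (100.9 to 194.2 CPM) overlapped air (138 to 259.6 CPM), and was at most 85.73 CPM in the combined group. The change of the 9 genes with silica is not given here, so a response particular to smoke is not shown. Hormone was not measured, and most of the 9 genes did not pass alone. Per1, 1 of the 9, was also on the clock list. The labels give no time of tissue collection, so it cannot be separated from smoke here either.

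Median changes of clock genes that peak at opposite times had opposite signs in the smoke comparisons. Without the 3 libraries the median log2 fold change was 1.29 for genes that peak with Dbp and -0.45 for genes that peak with Arntl in smoke against air, and 1.202 and -0.763 in the combined group against silica. In smoke against air the only gene of the Arntl side that passed was Arntl (edgeR adjusted p = 0.0266), and Cry1 (0.189), Clock (0.426) and Npas2 (0.592) did not. The 3 libraries did not make the pattern: 7 clock genes were called in either smoke comparison with them and 7 without. A different time of day of tissue collection predicts opposite phases as a smoke effect on the clock does, so the -0.45 separates neither, and the labels give no collection times.

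Other splits of the libraries, 60 for each comparison with the real one counted, show how often a regrouping reached the real count. They are a random sample of the possible splits. With silica against air 422 genes were called and at most 204 in another split, so 1 split reached the real count. Smoke against air gave 20 and at most 4 (1 split), the combined group against air 2987 and at most 907 (1 split), and the combined group against smoke 1720 and at most 512 (1 split). In each of these the real split alone reached its count, a share of 1 in 60, under 0.05. The other splits mix animals of both groups, so their counts are not those of data without an effect. The combined group against silica gave 33, and 2 splits reached that count, the other with 72 genes, over 2 times the real count. A share of 2 in 60 is under 0.05, but it rests on the splits drawn, and a regrouping called more genes than the real one. Chance is therefore not called excluded here, and why the other split called more was not tested. For the interaction, with 0 genes called by edgeR (977 at an unadjusted p under 0.05, DESeq2 1, voom 0), all 60 splits reach a count of 0 whatever the data, so this comparison says nothing about chance, and the highest other split called 17.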
